A study of Homo sapiens with 24 samples.

How the data were processed

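Gene expression was measured by RNA-seq in 24 libraries of the human ovarian cancer cell lines SKOV3 and OVCAR3, 12 per line. Per the labels, total RNA was purified on columns with DNase treatment and made into stranded mRNA libraries, SKOV3 cells grew in a mixed DMEM and Ham's F12 medium and OVCAR3 cells in RPMI medium, both with fetal bovine serum. The deposited files held raw counts of read pairs per gene, 1 library per file. Per the file headers, the authors counted pairs with featureCounts 1.5.1 on the reverse strand, with both ends aligned and chimeric pairs left out, on GENCODE 31 for SKOV3 and GENCODE 35 for OVCAR3. Per the submitters' processing notes the reads were aligned with STAR to GRCh38, and the version of STAR is not given in the sources used here. Pairs that aligned to several places were not asked for in the counting, so genes with near-identical copies, such as HLA, histone and ribosomal protein genes, can be undercounted. As the annotation differs between the lines, the lines were joined by gene identifier (60463 shared, 91.1% with the same version). Of 60603 and 60656 identifiers, 60306 and 60445 had a symbol in the gene name table.

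Libraries were grouped by the labels as SKOV3 wild type, SKOV3 knockout, OVCAR3 with empty vector and OVCAR3 with ZIC2 vector, 6 each. The header of each of the 12 SKOV3 files carried the name of the other group, and the labels were kept. No 2 libraries of a group were alike within sampling noise, as the lowest chi-square per gene between any 2 was 3.95 in SKOV3 and 3.12 in OVCAR3. Total counts ranged from 13310466 to 30114091 in SKOV3 and from 29747596 to 58208791 in OVCAR3, and intervals and floors cover counting error only.

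Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, default filterByExpr) in R 4.3.3, two-sided, within each line without covariates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and its standard error was taken from the fold change and the F statistic. The common biological coefficient of variation was 0.168 in SKOV3 and 0.100 in OVCAR3. The difference between the lines was a contrast in a fit of all 24 libraries, and genes called in both lines were compared with Fisher's exact test. CPM are the values of edgeR's cpm function on the library size scaled by TMM. Against a group at 0 counts a fold was computed with a floor of 3 counts over the group, and with 1 to 3 counts a ratio was given with an exact 95% interval. Gene lists, 36 written from textbook knowledge, were tested with camera (limma 3.58.1, voom, preset correlation), with an estimated correlation and fry as alternatives, where at least 3 members were measured, which was the case for 34 lists in SKOV3 and 36 in OVCAR3. Genes were named by a rule: ZIC2 and measured members of its family, the 8 largest changes each way per line with no overlap of the groups and a mean of at least 5 CPM, up to 4 called members per list by p, and 5 genes in each direction of the contrast and of each class of genes called in both lines. A list and some genes are not reported here. The tests, lists, rule and 12 of the alternatives were fixed before the data were examined.

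Alternatives were DESeq2 1.42.0, relative log expression and upper quartile factors, no filter and a stricter filter on low counts (1 CPM in 6 libraries), the replicate number as a block, limma-voom, all 24 libraries in a single fit, and each library left out. Whether replicate numbers pair libraries was checked by the correlation of deviations from the group means over genes. In SKOV3 it was above 0.1 for every number (0.102 to 0.690, mean 0.320, against -0.0585 between different numbers), with 9 of 12 libraries closest to their own number, and the pairing comes from the data and not from the labels. The window test placed fold changes at random 1000 times. On simulated counts with known changes, edgeR recovered 56.1% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes among 15013 genes in SKOV3 with 8 false calls (4.73% of its calls). There the replicate block made 14 false calls (8.43%), limma-voom 10 (5.99%) and DESeq2 49 (22.5%), and in OVCAR3 they made 8, 6 and 15. DESeq2 was run on other gene sets, of 15102 and 16989 genes. The simulated libraries carried no replicate effect, so the false calls of the block do not measure its use on paired libraries. Only 64 to 67 genes were changed per fold size, far fewer than the genes called in the data. In OVCAR3 edgeR without the block recovered 74.6%, 90.9% and 98.5% among 16768 genes with 5 false calls, and for the contrast of the lines 62.7%, 83.6% and 100% among 14091 genes with 13 false calls. A planted shift of 1.3-fold in a list was found in both lines (camera adjusted p 1.94e-28 and 6.54e-72) with 0 other lists, and 8 of 8 planted windows were found. The simulated genes were drawn independently, while the estimated correlation in the data reached 0.897 for G2/M genes in SKOV3. The 0 other lists therefore do not measure camera's false calls in the data.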

Results

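RNA-seq gene counts were collected from 24 libraries of 2 human ovarian cancer cell lines, SKOV3 and OVCAR3, with 6 libraries in each of 4 groups. SKOV3 libraries were labelled wild type for ZIC2 or ZIC2 knockout, and OVCAR3 libraries came from cells with an empty vector or with a vector for ZIC2 overexpression. ZIC2 encodes a zinc-finger transcription factor of the ZIC family, known for its part in neural development. The question named by the series is whether what ZIC2 does in ovarian cancer cells depends on their context, here the cell line. The total count per library ran from 13510068 to 30114091 in the libraries labelled wild type and from 13310466 to 23846970 in those labelled knockout. It ran from 32286370 to 58208791 with the empty vector and from 29747596 to 39327945 with the ZIC2 vector. Mitochondrial genes took 2.09% ± 0.25, 2.07% ± 0.483, 1.41% ± 0.255 and 1.31% ± 0.196 of the counts in these groups (SD, n = 6 each). The labels call the libraries biological replicates without naming clones, cultures or days, so the p-values measure the spread between these libraries, which may be partly technical.

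ZIC2 mRNA was higher in the SKOV3 libraries labelled knockout than in those labelled wild type, and far higher in OVCAR3 with the ZIC2 vector than with the empty vector. ZIC2 (ENSG00000043355.12) lies on chromosome 13 from 99981784 to 99986765, plus strand, in GRCh38. In SKOV3 it had 37.3 ± 4.55 CPM (counts scaled to library size) in the libraries labelled wild type and 82.2 ± 15.5 CPM in those labelled knockout (SD, n = 6 each), a 2.20-fold difference. The libraries labelled wild type spanned 32.2 to 43.8 CPM and those labelled knockout 61.8 to 98.2 CPM. The log2 fold change was 1.14 ± 0.12 (SE) with an adjusted p of 5.89e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An exact permutation test of the CPM over 924 splits, two-sided, gave p = 0.00216, the smallest those splits allow. The splits treat the 12 libraries as unpaired, though the replicate numbers pair them in SKOV3. Exchange within pairs alone would allow fewer splits and no p as small. The ZIC2 level thus went against the SKOV3 labels, and the header of each of the 12 SKOV3 count files carried the name of the other group. The SKOV3 groups are therefore called by their labels throughout, and every SKOV3 direction is that of the libraries labelled knockout, which held more ZIC2 mRNA, except in the contrast and the correlation of the lines and in the shares of genes with the same or opposite signs.

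In OVCAR3, ZIC2 rose from 2.20 ± 0.556 CPM with the empty vector to 155 ± 18.7 CPM with the ZIC2 vector (SD, n = 6 each), a log2 fold change of 6.13 ± 0.14 with an adjusted p of 1.11e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact two-sided permutation test gave p = 0.00216 here too. Its family member ZIC1 fell from 27.9 ± 1.43 to 15.5 ± 1.60 CPM (log2 -0.84 ± 0.07). ZIC4 stood at 0.695 ± 0.153 and 0.469 ± 0.179 CPM and did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0765). Of the ZIC family, 1 of 3 measured members was higher and 1 lower (2 adjusted over the list alone). In SKOV3 only ZIC2 and its chromosome neighbour ZIC5 had enough counts to test. Of these 1 was higher (1 adjusted over the list alone), and ZIC5 had 15.3 ± 1.12 CPM under the wild type label and 15.5 ± 1.42 CPM under the knockout label (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.859).

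**Figure D1:**
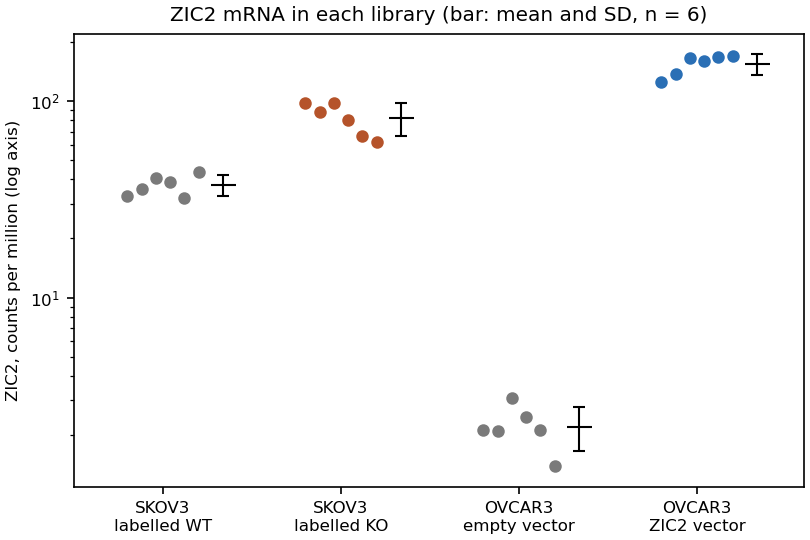
ZIC2 CPM on a log axis for each of the 24 libraries, with the mean and SD of each group of 6 beside its points. SKOV3 libraries labelled WT lie between 32.2 and 43.8 CPM and those labelled KO between 61.8 and 98.2 CPM, while OVCAR3 libraries lie at 1.38 to 3.09 CPM with the empty vector and at 126 to 171 CPM with the ZIC2 vector.

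The SKOV3 libraries labelled knockout had much more ALDH1A1, COL1A2, COL5A2 and MMP1 mRNA and much less MUC16, KRT7, KRT19 and SOX9 mRNA than the libraries labelled wild type. ALDH1A1, a retinaldehyde dehydrogenase used as a stem cell marker, had 0.0676 ± 0.10 CPM under the wild type label and 63.3 ± 38.3 CPM under the knockout label (SD, n = 6 each). MUC16, which encodes the CA125 antigen of ovarian tumours, went from 16.1 ± 3.94 to 0.239 ± 0.143 CPM. KRT7 and KRT19, keratins of simple epithelia, went from 3544 ± 566 to 403 ± 84.1 CPM and from 1035 ± 126 to 84.5 ± 20.7 CPM. COL5A2, a fibrillar collagen chain, went from 5.35 ± 1.51 to 251 ± 80.5 CPM.

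Of 15102 genes tested, 6758 changed in SKOV3 at an adjusted p under 0.05, 3345 of them higher and 3413 lower in the libraries labelled knockout. With upper quartile factors 3872 were higher and 2751 lower, so the balance of directions depended on the scaling. At least 2-fold changes numbered 1870, with 1227 higher and 643 lower. The CPM ranges of the groups did not overlap in 3717 of the changed genes and in 24.7% of all genes tested. Chance alone separates 0.216% of genes with 6 libraries against 6 if the libraries are not paired, which the replicate numbers in SKOV3 put in doubt. The first principal component held 71.3% of the variance and separated the labelled groups, and the second held 11.7% and set the libraries numbered 3 of both groups apart from the rest. NEFH, a neurofilament gene, CCND2, a G1 cyclin, LRRN3 and MMP3, a stromelysin, had 0 counts over the 6 libraries labelled wild type. Against a floor of 3 counts over the group they were at least 1854-fold, 1265-fold, 932-fold and 912-fold higher under the knockout label. MUC15, EMB and TMEM30B had 1, 1 and 3 counts under the wild type label, with ratios of 2745 (95% exact counting interval 492 to 108450), 1172 (210 to 46312) and 1732 (592 to 8400). The genes with the largest falls were CBLN2 at a log2 fold change of -8.35 ± 0.77, MUC16 at -6.08 ± 0.29, ARHGDIB at -5.64 ± 0.31, IGFBP5 at -5.38 ± 0.63 and BIRC7 at -4.75 ± 0.35. RXFP1, EDN2 and ANKRD1 followed between -4.62 and -4.21. IGFBP5 varied widely under the wild type label, at 257 ± 217 CPM.

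Of 23 measured genes of cholesterol synthesis and uptake, 19 were lower in the SKOV3 libraries labelled knockout, 1 was higher and 3 did not pass the test (21 adjusted over the list alone). Among those lower were NSDHL (log2 -0.75 ± 0.08) and LSS (-1.0 ± 0.15). Camera gave the list an adjusted p of 1.62e-05 with its preset correlation, and adjusted p = 0.503 with an estimated correlation. Epithelial genes also leaned lower, 13 against 2 higher of 25 measured (15 adjusted over the list alone). KRT19 stood at -3.62 ± 0.15, KRT7 at -3.14 ± 0.16, the tight junction gene CLDN4 at -3.86 ± 0.24 and the transcription factor gene OVOL2 at -1.71 ± 0.16. Camera's adjusted p for them was 0.00199, and adjusted p = 0.503 with an estimated correlation. Integrins were lower in 11 and higher in 2 of 19 (15 adjusted over the list alone). ITGB6 stood at -2.19 ± 0.21 and ITGB3 at -1.34 ± 0.15 but ITGA7 at 3.13 ± 0.23. Genes of the Müllerian and ovarian lineage were lower in 10 and higher in 4 of 17 (14 adjusted over the list alone). The mesothelin gene MSLN stood at -1.60 ± 0.13 and the estrogen receptor gene ESR1 at -2.24 ± 0.24. The progesterone receptor gene PGR went the other way, from 3 counts over the libraries labelled wild type to 1085 under the knockout label, a ratio of 356 (95% exact counting interval 122 to 1729). Camera's adjusted p was 0.0323 for integrins and 0.0403 for the lineage genes, and adjusted p = 0.503 with an estimated correlation for both.

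Of 27 measured HOX genes 13 were higher and 1 lower in the SKOV3 libraries labelled knockout (14 adjusted over the list alone). HOXC10 stood at a log2 fold change of 6.29 ± 0.44, HOXC6 at 3.99 ± 0.32, HOXC9 at 3.91 ± 0.19 and HOXC8 at 3.67 ± 0.23. Camera gave an adjusted p of 0.00103, and adjusted p = 0.503 with an estimated correlation. Immediate-early and feedback genes of MAPK signalling were higher in 15 and lower in 2 of 23 (17 adjusted over the list alone). ETV1 stood at 3.61 ± 0.33 and SPRY1, a feedback inhibitor, at 2.80 ± 0.35. Their camera adjusted p was 0.00354, and adjusted p = 0.503 with an estimated correlation. Antigen presentation genes were higher in 10 and lower in 1 of 15 (12 adjusted over the list alone). HLA-B stood at 1.08 ± 0.22, HLA-C at 0.87 ± 0.15 and the peptide transporter gene TAP1 at 0.61 ± 0.12. Camera's adjusted p was 0.0103, and adjusted p = 0.594 with an estimated correlation, and HLA genes can share reads with near-identical copies. Genes of the chromosome 6 window from 30000001 to 40000000, which holds the HLA genes, had a median log2 fold change of 0.39. Hedgehog pathway genes were higher in 8 and lower in 1 of 14 (9 adjusted over the list alone). GLI1, both an effector and a target, stood at 1.84 ± 0.19 and the co-receptor gene BOC at 1.3 ± 0.13 (camera adjusted p 0.0403, adjusted p = 0.503 with an estimated correlation). Wnt/beta-catenin targets were higher in 7 and lower in 2 of 14 (9 adjusted over the list alone), with AXIN2 at 3.24 ± 0.25 and NKD1 at 2.23 ± 0.12. Their camera adjusted p was 0.0190, and 0.0725 with the replicate number as a block, so that the call ended, and adjusted p = 0.503 with an estimated correlation.

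The other lists did not pass camera in SKOV3, with adjusted p between 0.118 and 0.823, although many of their members changed in opposite directions. Collagen and basement membrane genes were higher in 9 and lower in 16 of 30 (25 adjusted over the list alone): COL5A2 (log2 5.53 ± 0.26) and COL1A2 (5.22 ± 0.35) rose while the basement membrane chains COL4A1 (-1.91 ± 0.12) and COL4A2 (-1.43 ± 0.10) fell. Mesenchymal genes were higher in 7 and lower in 9 of 24 (17 adjusted over the list alone). ZEB2, a repressor of epithelial genes, stood at 3.48 ± 0.18, the smooth muscle actin gene ACTA2 at 4.63 ± 0.39 and TGFBI at -2.67 ± 0.21. Matrix proteases and inhibitors were higher in 10 and lower in 8 of 26 (22 adjusted over the list alone). MMP1 stood at 4.90 ± 0.46, MMP10 at 4.53 ± 0.45 and MMP2 at -2.24 ± 0.19. The list's median was 0.11 both as fitted and with MMP3 at its lower bound. Stem cell markers were higher in 6 and lower in 5 of 18 (11 adjusted over the list alone), with the receptor gene KIT at 3.28 ± 0.29 and SOX9 at -3.54 ± 0.37. TGF-beta targets were lower in 11 and higher in 3 of 18 (14 adjusted over the list alone). Notch pathway genes were higher in 7 and lower in 3 of 15 (10 adjusted over the list alone), with HEYL at 3.53 ± 0.30. All 9 measured neural genes changed, 6 higher and 3 lower (9 adjusted over the list alone), with PAX6 at 2.96 ± 0.35 and MAP2 at -2.13 ± 0.23. Receptor tyrosine kinases and ligands were lower in 16 and higher in 7 of 34 (23 adjusted over the list alone), with IGF1R at -1.52 ± 0.12 and IGFBP2 at 3.29 ± 0.19.

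Few cell cycle genes passed the test in SKOV3, where 3 of 25 G1/S and replication genes were higher and 1 lower (4 adjusted over the list alone), and 1 of 24 G2/M genes was higher and 2 lower (3 adjusted over the list alone). CDKN1A, a cyclin-dependent kinase inhibitor gene, stood at a log2 fold change of 1.65 ± 0.26. Cell line identity genes were higher in 3 and lower in 2 of 9 (5 adjusted over the list alone). Hypoxia and glycolysis genes were lower in 11 and higher in 4 of 31 (16 adjusted over the list alone), with the glucose transporter gene SLC2A1 at -1.32 ± 0.10. Genes of the unfolded protein and integrated stress responses were lower in 11 and higher in 3 of 28 (14 adjusted over the list alone). Interferon response genes were higher in 7 and lower in 5 of 34 (11 adjusted over the list alone). Inflammatory genes were higher in 3 and lower in 4 of 23 (7 adjusted over the list alone). Apoptosis regulators were higher in 10 and lower in 4 of 25 (14 adjusted over the list alone). NRF2 targets were higher in 4 and lower in 6 of 20 (11 adjusted over the list alone). Drug efflux transporter genes were higher in 4 and lower in 3 of 15 (7 adjusted over the list alone), with ABCB1, which encodes P-glycoprotein, at 2.87 ± 0.31. Heat shock genes were higher in 2 and lower in 6 of 16 (8 adjusted over the list alone). Ribosomal protein genes were higher in 7 and lower in 18 of 36 (27 adjusted over the list alone). Histone genes were higher in 2 of 11 (2 adjusted over the list alone), and none of 13 mitochondrial mRNAs passed (0 adjusted over the list alone). Of other cell types, 1 leukocyte gene of 16 was measurable, and it was higher (1 adjusted over the list alone). Fibroblast and mesothelial markers were higher in 3 and lower in 2 of 6 (5 adjusted over the list alone). Endothelial markers were higher in 2 of 3 (2 adjusted over the list alone). The fibroblast genes COL3A1, DCN and LUM had 2, 3 and 5 counts over the libraries labelled wild type and 75, 13 and 52 counts under the knockout label, and were named after their values were seen.

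The median and the mean of a SKOV3 list differed in sign for stem cell markers (median -0.05, mean 1.05, camera up), mesenchymal genes (median -0.13, mean 0.62, camera down), collagens (median -0.61, mean 0.04, camera down), NRF2 targets (median -0.05, mean 0.04, camera down) and cell line identity genes (median 0.17, mean -0.66, camera down). With upper quartile factors the medians of stem cell markers and NRF2 targets turned to 0.0045 and 0.0052, and that of G2/M genes from -0.02 to 0.04. As the libraries labelled knockout held more ZIC2 mRNA, these directions are given by label and not as those of a loss of ZIC2.

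**Figure D2:**
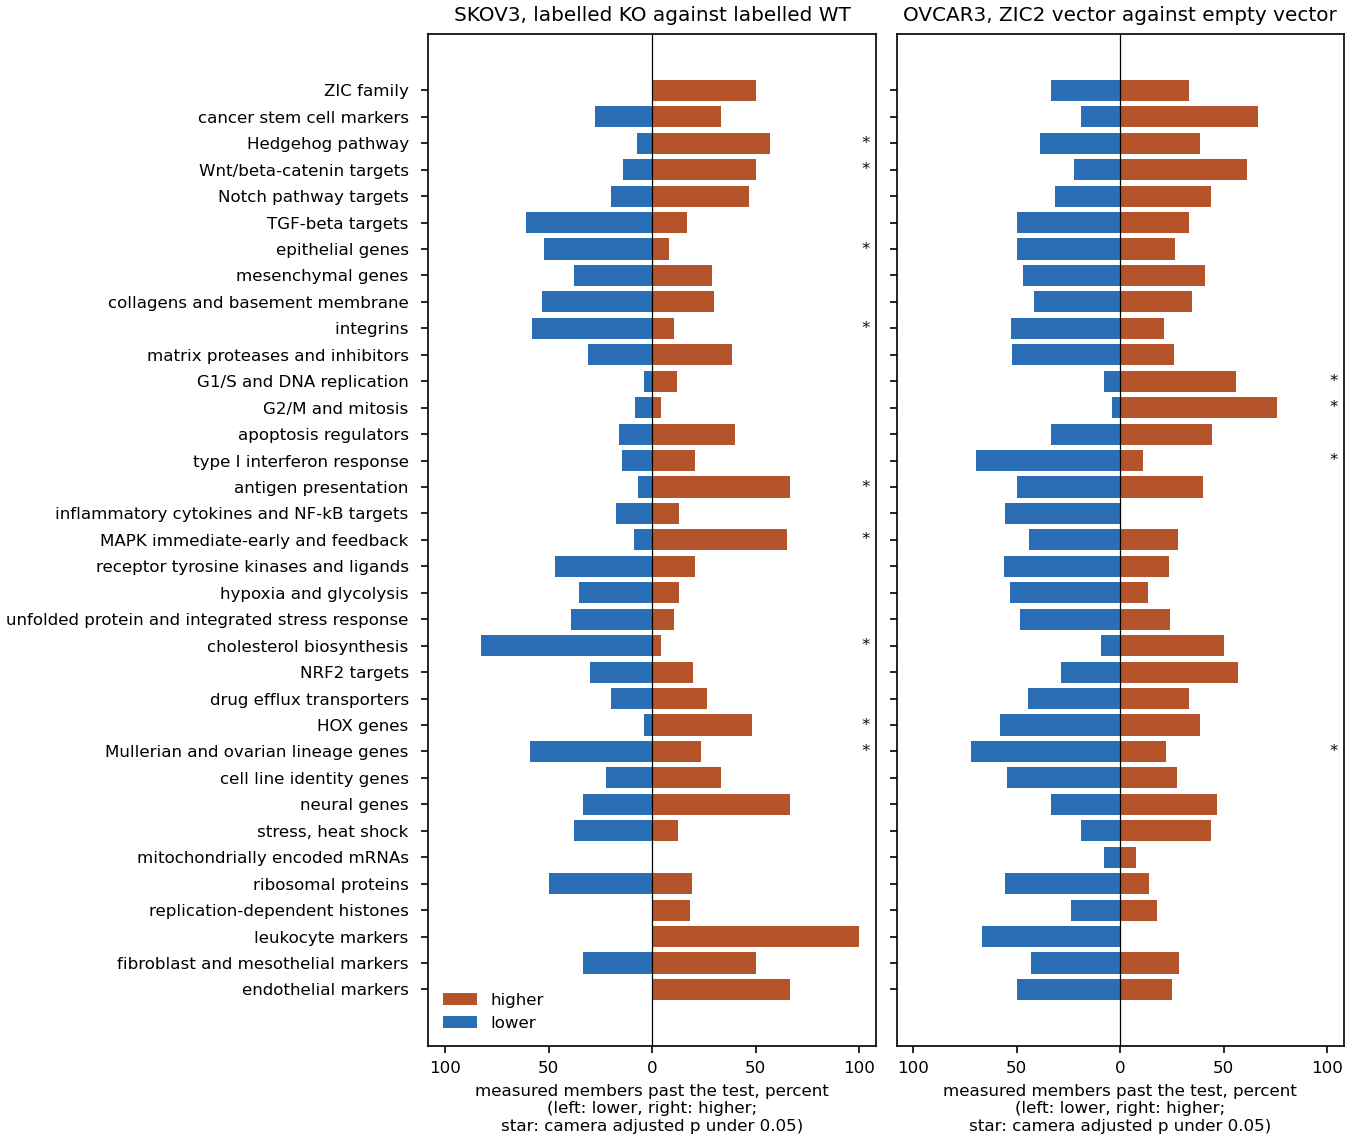
Share of the measured members of each gene list shown that passed edgeR's test, in percent, higher to the right and lower to the left, for SKOV3 libraries labelled KO against WT and for OVCAR3 with the ZIC2 vector against the empty vector. Stars mark the 9 and 4 lists past camera with its preset correlation, none of which passed with an estimated correlation, and cholesterol genes stand out in SKOV3 with 19 of 23 lower.

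OVCAR3 cells with the ZIC2 vector had more CDH2, LRP2, PCDH19 and SOX3 mRNA and less MMP2, MSLN, TXNIP and GAS6 mRNA than cells with the empty vector. CDH2, which encodes N-cadherin, rose from 5.4 ± 0.992 to 135 ± 8.04 CPM (SD, n = 6 each), and LRP2, which encodes the endocytic receptor megalin, from 2.29 ± 0.735 to 353 ± 90.4 CPM. MMP2, a gelatinase gene, fell from 93.9 ± 5.92 to 1.04 ± 0.351 CPM, and MSLN, the mesothelin gene, from 258 ± 20.5 to 20.7 ± 2.24 CPM. Of 25 genes of G2/M and mitosis 19 were higher, and of 36 interferon response genes 25 were lower.

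Of 16989 genes tested, 11677 changed in OVCAR3 at an adjusted p under 0.05, 5815 higher and 5862 lower with the ZIC2 vector. At least 2-fold changes numbered 2857, with 1090 higher and 1767 lower. The groups' CPM ranges did not overlap in 8224 of the changed genes and in 48.4% of all genes tested, against 0.216% of genes by chance. The first principal component held 82.5% of the variance and separated the groups, and the second held 4.91%. PCDH19, a protocadherin gene, rose from 0.0434 ± 0.0581 to 48.4 ± 11.4 CPM, IGFN1 from 0.125 ± 0.108 to 95.5 ± 19.6 CPM and MAN1A1, a Golgi mannosidase gene, from 0.127 ± 0.0631 to 34 ± 3.98 CPM. NRXN3 and PI15 had log2 fold changes of 7.79 ± 0.16 and 7.75 ± 0.24, and the chemokine gene CXCL14 one of 9.21 ± 0.87. SLC14A2 had 3 counts over the libraries with the empty vector and 2207 with the ZIC2 vector, a ratio of 816 (95% exact counting interval 279 to 3961). TXNIP, which encodes thioredoxin-interacting protein, had 3926 counts with the empty vector and 2 with the ZIC2 vector, a ratio of 1769 (490 to 14616). DLEC1, CACNG6, GABRE and KRT16 had log2 fold changes of -6.91 ± 0.17, -7.05 ± 0.32, -6.54 ± 0.23 and -6.45 ± 0.21. PI3 and S100A8 had log2 fold changes of -7.70 ± 1.32 and -6.49 ± 1.50. Their empty vector means of 133 ± 197 and 23.7 ± 40.6 CPM rested mainly on libraries 1 and 2. Neither passed with limma-voom (limma, Benjamini-Hochberg adjusted p = 0.0510 and 0.0840).

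Of 25 G2/M genes 19 were higher and 1 lower with the ZIC2 vector in OVCAR3 (21 adjusted over the list alone). The mitotic kinesin gene KIF20A stood at a log2 fold change of 0.89 ± 0.08, the kinase gene TTK at 0.61 ± 0.06 and the checkpoint gene BUB1B at 0.55 ± 0.05, and none of the list changed 2-fold. Camera gave an adjusted p of 0.00160, and adjusted p = 0.939 with an estimated correlation. Of 25 G1/S and replication genes 14 were higher and 2 lower (16 adjusted over the list alone). E2F1 stood at 1.03 ± 0.08 and the helicase subunit gene MCM3 at 0.78 ± 0.07 (camera adjusted p 0.0443, adjusted p = 0.939 with an estimated correlation). Interferon response genes were lower in 25 and higher in 4 of 36 (29 adjusted over the list alone). The antiviral gene MX2 stood at -6.42 ± 0.17, IFI27 at -2.39 ± 0.10 and IFITM3 at -1.38 ± 0.06. Camera gave them an adjusted p of 0.00160, and adjusted p = 0.537 with an estimated correlation. Müllerian and ovarian lineage genes were lower in 13 and higher in 4 of 18 (17 adjusted over the list alone). MSLN stood at -3.64 ± 0.08, MUC1 at -2.74 ± 0.13 and EMX2 at -1.69 ± 0.08 but the lineage factor gene PAX8 at 0.60 ± 0.04. Their camera adjusted p was 0.0351, and adjusted p = 0.772 with an estimated correlation.

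The other 32 lists did not pass camera in OVCAR3, with adjusted p between 0.0786 and 0.968. Among mesenchymal genes 7 were higher and 8 lower of 17 (15 adjusted over the list alone). CDH2 stood at a log2 fold change of 4.63 ± 0.10, TWIST1 at 2.85 ± 0.13 and VIM, which encodes vimentin, at 1.94 ± 0.08. Epithelial genes were lower in 15 and higher in 8 of 30 (23 adjusted over the list alone). The plakophilin gene PKP3 stood at -1.44 ± 0.05 and CDH1, which encodes E-cadherin, at -0.64 ± 0.06. Matrix proteases and inhibitors were lower in 12 and higher in 6 of 23 (20 adjusted over the list alone), with MMP2 at -6.51 ± 0.14. Integrins were lower in 10 and higher in 4 of 19 (14 adjusted over the list alone), with ITGA4 at -3.98 ± 0.14 and ITGB2 at -3.38 ± 0.14. Collagens were higher in 10 and lower in 12 of 29 (22 adjusted over the list alone). COL1A2 went from 214 counts with the empty vector to 0 with the ZIC2 vector, at least 64.3-fold lower against the floor of 3 counts over the group. Setting COL1A2 at its bound left the median of the collagens at 0.12 and that of the fibroblast markers at -0.06. HOX genes went both ways, with 12 higher and 18 lower of 31 (30 adjusted over the list alone): HOXB2 (4.34 ± 0.09), HOXB4 (2.68 ± 0.09) and HOXB3 (1.69 ± 0.06) rose and HOXA9 (-4.37 ± 0.11) fell. Neural genes were higher in 7 and lower in 5 of 15 (13 adjusted over the list alone). The neural progenitor factor gene SOX3 stood at 6.99 ± 0.16, EPHB1 at 6.71 ± 0.18 and the adhesion gene L1CAM at -1.72 ± 0.08. Receptor tyrosine kinases and ligands were lower in 19 and higher in 8 of 34 (27 adjusted over the list alone), with GAS6, a ligand of the AXL receptor family, at -5.21 ± 0.14.

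Stem cell markers were higher in 14 and lower in 4 of 21 in OVCAR3 (19 adjusted over the list alone), with LIN28B at a log2 fold change of 4.25 ± 0.19 and CD24 at -2.23 ± 0.12. Inflammatory genes were lower in 15 and higher in 0 of 27 (15 adjusted over the list alone), with the adhesion gene ICAM1 at -1.09 ± 0.14. Hedgehog genes were higher in 5 and lower in 5 of 13 (12 adjusted over the list alone), with the receptor gene PTCH1 at 1.46 ± 0.08 and GLI3 at -0.98 ± 0.09. Wnt/beta-catenin targets were higher in 11 and lower in 4 of 18 (15 adjusted over the list alone), with AXIN2 at 1.91 ± 0.11 and NKD1 at -2.38 ± 0.20. Notch genes were higher in 7 and lower in 5 of 16 (12 adjusted over the list alone), with HEY1 at 3.32 ± 0.11. TGF-beta targets were higher in 6 and lower in 9 of 18 (15 adjusted over the list alone). Cholesterol genes were higher in 11 and lower in 2 of 22 (13 adjusted over the list alone). Hypoxia and glycolysis genes were lower in 16 and higher in 4 of 30 (20 adjusted over the list alone). Genes of the unfolded protein and integrated stress responses were lower in 14 and higher in 7 of 29 (21 adjusted over the list alone). NRF2 targets were higher in 12 and lower in 6 of 21 (18 adjusted over the list alone). MAPK genes were higher in 7 and lower in 11 of 25 (18 adjusted over the list alone). Apoptosis regulators were higher in 12 and lower in 9 of 27 (23 adjusted over the list alone), with BCL2 at 2.67 ± 0.14. Antigen presentation genes were higher in 8 and lower in 10 of 20 (18 adjusted over the list alone). Drug efflux genes were higher in 6 and lower in 8 of 18 (14 adjusted over the list alone). Cell line identity genes were higher in 3 and lower in 6 of 11 (9 adjusted over the list alone). Heat shock genes were higher in 7 and lower in 3 of 16 (10 adjusted over the list alone). Histone genes were higher in 3 and lower in 4 of 17 (7 adjusted over the list alone). Mitochondrial mRNAs were higher in 1 and lower in 1 of 13 (0 adjusted over the list alone). Ribosomal protein genes were lower in 20 and higher in 5 of 36 (25 adjusted over the list alone), with RPS3 at -0.91 ± 0.03 and RPS16 at 0.76 ± 0.04. Markers of leukocytes were lower in 2 of 3 (2 adjusted over the list alone). Those of fibroblasts and mesothelium were higher in 2 and lower in 3 of 7 (5 adjusted over the list alone). Those of endothelium were higher in 2 and lower in 4 of 8 (6 adjusted over the list alone). The median and the mean of an OVCAR3 list differed in sign for the ZIC family (median -0.55, mean 1.58, camera up), mesenchymal genes (median 0.14, mean -0.20, camera up), collagens (median 0.12, mean -0.35, camera down), neural genes (median -0.22, mean 1.08, camera up) and apoptosis regulators (median 0.10, mean -0.04, camera up).

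Genes were also compared by position, in windows of 10 Mb with at least 10 genes of at least 10 CPM. In OVCAR3, 52 of 273 windows had a median log2 fold change beyond 0.3 in size, 36 higher and 16 lower, against at most 10 in 1000 random placements of the fold changes. All windows of chromosome 6 from 1 to 60000000 were higher, up to a median of 0.86 between 50000001 and 60000000, and those of chromosome 22 from 10000001 to 60000000 were lower, with medians from -0.41 to -0.67. In SKOV3, 16 of 276 windows passed the same limit, 9 higher and 7 lower in the libraries labelled knockout, against at most 4 in random placements. They included chromosome 19 from 30000001 to 60000000, with medians from 0.33 to 0.37, and chromosome 6 from 30000001 to 40000000, at 0.39. In OVCAR3 the window of chromosome 11 from 1 to 10000000 was lower too, at -0.65. Of the called genes in windows, 24.7% in OVCAR3 and 11.7% in SKOV3 lay in shifted windows, against 21.5% and 7.98% of all genes in windows. The gene lists were not adjusted for these shifts, so part of a member's change can be that of its region.

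**Figure D3:**
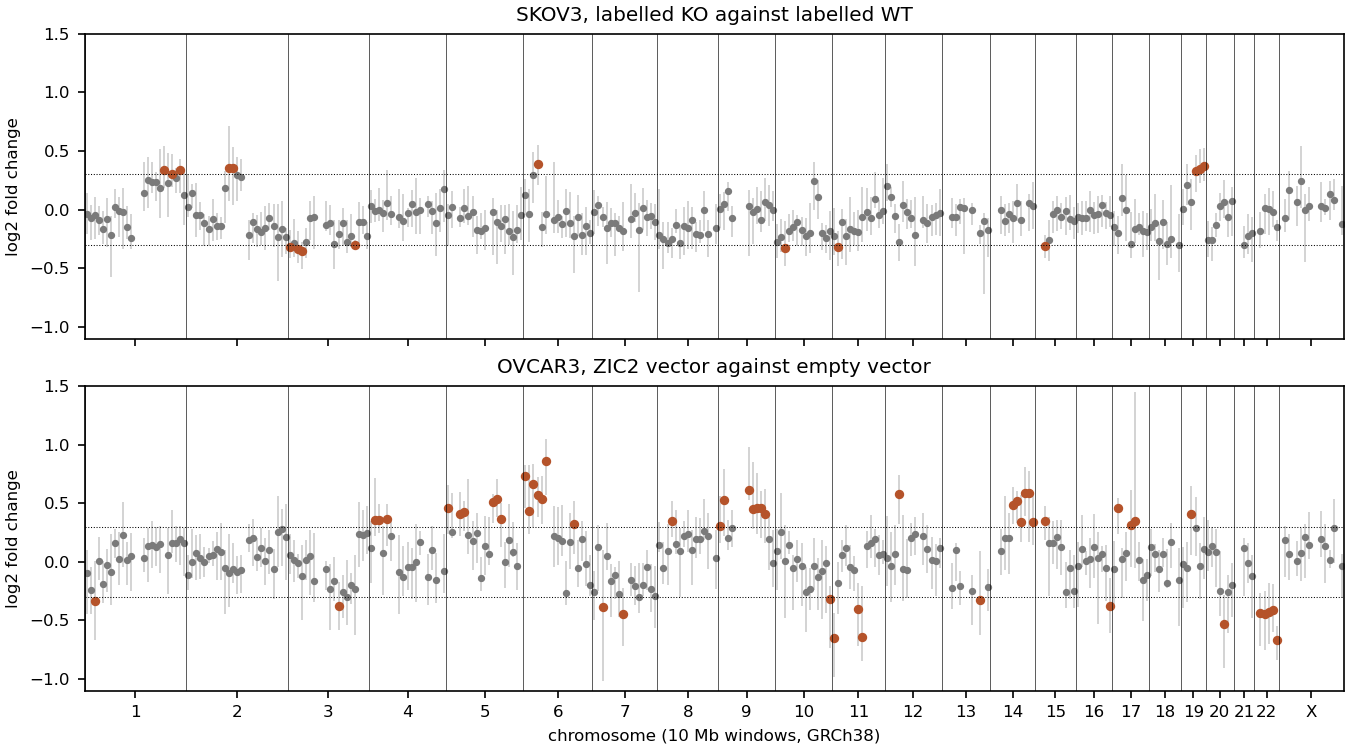
Median log2 fold change (points) and quartiles (grey lines) of genes in windows of 10 Mb along chromosomes 1 to 22 and X, for SKOV3 libraries labelled KO against WT and for OVCAR3 with the ZIC2 vector against the empty vector. Coloured points lie beyond the dotted lines at 0.3 in size, 16 of 276 windows in SKOV3 and 52 of 273 in OVCAR3, with chromosome 6 up to 0.86.

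The effects of the ZIC2 manipulations differed between the lines with either sign of the SKOV3 effect for TLE4, HOXB2, IGFN1, EHD2, PORCN and PARVA. Each of these genes changed in the same direction in the libraries with more ZIC2 mRNA of either line, and by more in OVCAR3. With the turned sign their differences are thus of size and not of direction. ZIC2 itself differed by a log2 of 1.14 in SKOV3 and 6.13 in OVCAR3. The differences for ADD2 and WNT10A changed sign with the sign taken for SKOV3, and that for UNC13D passed the test with the labelled sign alone. The comparison asked whether the effect depends on the line, with the SKOV3 effect taken as labelled wild type minus labelled knockout and the OVCAR3 effect as ZIC2 vector minus empty vector. TLE4, a co-repressor gene, differed by a log2 of 5.57 ± 0.15, from -0.71 ± 0.11 in SKOV3 to 4.87 ± 0.09 in OVCAR3, and HOXB2 by 4.74 ± 0.13. IGFN1 and the adducin gene ADD2 differed by 14.68 ± 0.46 and 6.40 ± 0.18, and ZIC2 itself by 7.27 ± 0.20. UNC13D, a gene of vesicle priming, differed by -6.85 ± 0.14, with 3.42 ± 0.11 in SKOV3 and -3.44 ± 0.08 in OVCAR3. Negative differences were also found for EHD2 at -7.06 ± 0.19, WNT10A at -6.31 ± 0.17, PORCN, needed for Wnt secretion, at -4.62 ± 0.14 and PARVA at -3.08 ± 0.09.

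The SKOV3 effect was also turned to labelled knockout minus labelled wild type, a choice made after ZIC2 was seen to go against the labels. The difference was then 4.15 ± 0.15 for TLE4, 3.92 ± 0.13 for HOXB2, 4.03 ± 0.54 for IGFN1 and 4.99 ± 0.20 for ZIC2. It was -5.81 ± 0.19 for EHD2, -1.77 ± 0.14 for PORCN and -1.87 ± 0.09 for PARVA. ADD2 went to -2.40 ± 0.18 and WNT10A to 0.63 ± 0.16.

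Of 18387 genes tested over all 24 libraries, 9808 differed between the lines by edgeR's quasi-likelihood test of the contrast, 4954 in the positive and 4854 in the negative direction. With the sign of the SKOV3 effect turned, 9361 genes differed, and 5975 passed both ways. Passing both ways asks that the effects differ in size, whatever their directions. For UNC13D the turned difference was -0.03 ± 0.13 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.866), and it was lower in the libraries with more ZIC2 mRNA in both lines. Camera's adjusted p with the labelled sign was 0.0160 for epithelial genes, 0.0160 for ribosomal proteins, 0.0205 for Müllerian lineage genes, 0.0276 for receptor tyrosine kinases and ligands and 0.0378 for cholesterol genes, each with a negative difference of effects. They gave adjusted p = 0.743 with an estimated correlation for epithelial, lineage and receptor genes, and 0.838 for ribosomal and cholesterol genes. Fry, which tests a list against no change, gave each of these lists an adjusted p of at most 0.0124. With the turned sign camera passed cholesterol genes (adjusted p 1.87e-05), epithelial genes (0.0492) and G2/M genes (0.0492) with a positive difference. Interferon (0.0339), MAPK (0.0492) and antigen presentation genes (0.0492) passed with a negative difference. They gave adjusted p = 0.951 with an estimated correlation for G2/M genes, 0.831 for interferon genes and 0.807 for the others of these lists. Ribosomal, lineage and receptor genes did not pass with it (camera adjusted p 0.726, 0.559 and 0.932). The directions for epithelial and cholesterol genes in this contrast thus depend on the SKOV3 labels. The lines also differed in medium and in the kind of manipulation, which cannot be told apart from the line. The same holds for the size of the ZIC2 difference, a log2 of 1.14 in SKOV3 and 6.13 in OVCAR3. A gene that follows ZIC2 alike in both lines can therefore differ in this contrast. The lines were not matched for the ZIC2 level. They differed in the gene annotation used for counting too. With identifiers of the same version in both annotations, a choice made after the data were seen, 7624 of 14679 genes differed, 7577 of them among the 9808.

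Among genes called in both lines, COL5A2, SFRP1 and IGFN1 were higher and MUC16, MMP2, CRYAB and UNC13D lower in the libraries with more ZIC2 mRNA of either line. COL5A2 had log2 fold changes of 5.53 ± 0.26 in the SKOV3 libraries labelled knockout and 3.96 ± 0.17 with the ZIC2 vector in OVCAR3. SFRP1, a secreted Wnt antagonist gene, had 5.30 ± 0.28 and 2.41 ± 0.12, with NPR3 and AKAP6 next. MUC16 had -6.08 ± 0.29 and -3.05 ± 0.48, the small heat shock gene CRYAB -4.01 ± 0.43 and -2.80 ± 0.11, and MMP2 -2.24 ± 0.19 and -6.51 ± 0.14. Other genes went opposite ways in the libraries with more ZIC2 mRNA. The RNA-binding protein gene IGF2BP1 rose by 6.81 ± 0.41 in the SKOV3 libraries labelled knockout and had -3.72 ± 0.08 in OVCAR3, and KIF1A, CILP2, FN1 and ALDOC went the same way as IGF2BP1. The endothelin gene EDN1 had -1.89 ± 0.25 and 6.12 ± 0.22, and LRRC17, DYSF, DAPK1 and ADAMTS15 went the same way as EDN1.

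In total 4605 of 14091 genes tested in both lines were called in both, where independent lists would share 4381. Of them 1255 were higher in the libraries labelled knockout and with the ZIC2 vector (1088 for independent lists), 1359 were lower in both (1101). Another 1013 were higher under the knockout label and lower with the ZIC2 vector (1044), and 978 the reverse (1148). With the SKOV3 effects taken as labelled wild type minus labelled knockout, 1991 genes (43.2%) had the same sign in both lines and 2614 (56.8%) had opposite signs. Fisher's exact test of the directions, with SKOV3 as labelled knockout over labelled wild type, gave an odds ratio of 1.72 (95% interval 1.53 to 1.94), p = 5.48e-20, over genes, which are not independent replicates. Of genes changed at least 2-fold, 615 were called in both, where independent lists would share 187. Across the 14091 genes the fold changes of the 2 lines, with SKOV3 as labelled wild type minus labelled knockout, had a Pearson correlation of -0.06 and a Spearman correlation of -0.08.

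**Figure D4:**
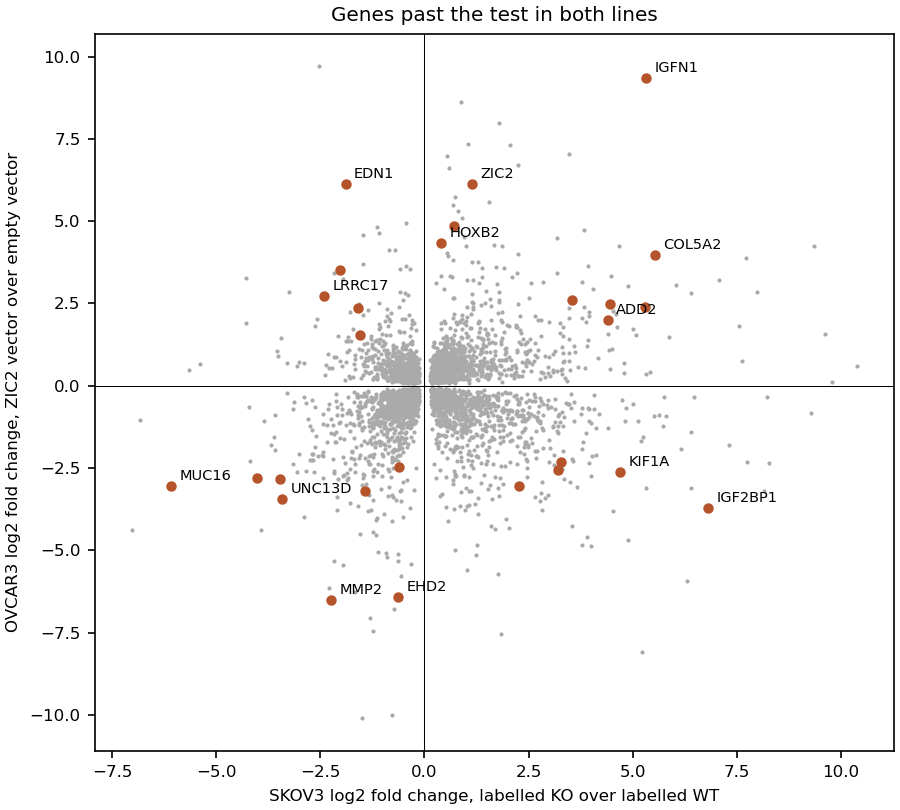
Log2 fold changes of the 4605 genes past edgeR's test in both lines, SKOV3 libraries labelled KO over WT on the horizontal axis and OVCAR3 with the ZIC2 vector over the empty vector on the vertical axis, as fitted. Coloured points are genes named by rule, 1255 genes lie at upper right with IGFN1 and COL5A2, and 1359 lie at lower left with MUC16 and MMP2.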

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

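Of the tests in this part, both on the SKOV3 labels, that of the turned effect and the interval for exon length were chosen only after the result was seen.

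ZIC2 mRNA went against the SKOV3 labels, with more in the libraries labelled knockout. An exchange of the labels of both groups may account for it: the header of 12 of 12 SKOV3 count files carried the name of the other group, and the CPM ranges of the groups did not overlap. A knockout that leaves or raises the mRNA, with correct labels, cannot be told apart from this by the 2.20-fold difference, since gene counts do not show the edited base or the protein. No value here decides which of the names is right, so the biological reading of every SKOV3 direction stays open.

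In both lines genes of the same chromosomal region shifted together. Copy-number differences between the populations of cells may account for this, as 16 windows in SKOV3 (at most 4 in 1000 random placements) and 52 in OVCAR3 (at most 10) had a median log2 fold change beyond 0.3 in size, each with a permutation p = 0.000999, the smallest the placements can give. DNA was not measured, and regulation of whole regions or an effect of ZIC2 itself was not tested, so these stay open. Of genes changed at least 2-fold, 90.9% in SKOV3 and 84.5% in OVCAR3 stayed at least 2-fold from the median of the other genes in their window. Shifts of the size of these medians thus leave most such changes. As most windows had medians within 0.3, that result was close to fixed in advance. Shifts over part of a window were not tested, so regional shifts as the source of most of these changes stay open.

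Ribosomal protein genes went both ways in OVCAR3, from RPS3 at a log2 fold change of -0.91 to RPS16 at 0.76. Across 36 such genes, which are not independent replicates, the change followed the median of the other genes of the window (Pearson r = 0.762, Spearman rho = 0.703, permutation p = 1e-05 for both, the smallest 100000 resamples can give, and Benjamini-Hochberg adjusted p = 2e-05 for r over the 2 relations tested), so regional shifts are a candidate explanation. For exon length r was -0.173 (95% bootstrap interval over genes -0.454 to 0.147, permutation p = 0.314, Benjamini-Hochberg adjusted p = 0.314) and Spearman rho -0.255 (permutation p = 0.132). The interval passes the bar of 0.3 in size, so a length bias stays open. A direct effect of ZIC2 on these genes was not tested.

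A library far from the others of its group was found in 37 of 368 groups of values tested by Dixon's ratio, where chance marks about 1 in 20, or 18.4. That rate holds for normal and independent values, while these groups share libraries and some lie near 0 CPM. The excess over 18.4 is therefore hard to read. Of the 23 groups of CPM with such a library in SKOV3, 11 were set apart by a library numbered 3, which also stood apart on the second principal component. SKOV3 library 1 labelled wild type had CDKN1A at 8.30 CPM. SKOV3 library 3 labelled wild type had ALDH1A1 at 0.258, ALDOC at 35.7, AXIN2 at 0.602, COL5A2 at 8.34, MMP1 at 12.1 and PORCN at 94.3 CPM. SKOV3 library 4 labelled wild type had EMB at 0.0693, GLI1 at 1.94 and MUC15 at 0.0693 CPM. SKOV3 library 6 labelled wild type had CRYAB at 219, HEYL at 2.15, PARVA at 233, PTGS2 at 0.0704 and TMEM30B at 0.106 CPM. SKOV3 library 1 labelled knockout had CDKN1A at 34.3, CRYAB at 12.2 and ZEB2 at 20.4 CPM. SKOV3 library 3 labelled knockout had BIRC7 at 1.56, IGFBP5 at 16.5, ITGA7 at 19.3, ITGB6 at 16.5 and MMP1 at 410 CPM. OVCAR3 library 1 with the empty vector had LIN28B at 0.346, PI3 at 513 and S100A8 at 105 CPM. OVCAR3 library 2 with the empty vector had PCDH19 at 0.156 CPM. OVCAR3 library 5 with the empty vector had PKP3 at 188 CPM. OVCAR3 library 1 with the ZIC2 vector had CXCL14 at 43.0 and E2F1 at 203 CPM. OVCAR3 library 3 with the ZIC2 vector had CDH1 at 116, HOXA9 at 2.17 and TXNIP at 0.0556 CPM. OVCAR3 library 4 with the ZIC2 vector had GAS6 at 0.837 CPM. OVCAR3 library 6 with the ZIC2 vector had IGFN1 at 133 and MUC16 at 55.4 CPM. The values of EMB, MUC15 and TMEM30B rested on 1, 1 and 3 counts and that of TXNIP on 2, with 0 in the other libraries of the group. The total count of OVCAR3 library 2 with the empty vector was 58208791, above the others of its group.

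The effects of the manipulations differed between the lines by edgeR's test of the difference for 9808 genes. The ZIC2 difference itself was far larger in OVCAR3, which cannot be told apart from the line. Among the genes named, the difference in log2 fold change, with the SKOV3 effect by its labels, was 5.57 for TLE4, 4.74 for HOXB2, 6.40 for ADD2, 7.27 for ZIC2 and 14.68 for IGFN1. It was -6.85 for UNC13D, -6.31 for WNT10A, -3.08 for PARVA, -7.06 for EHD2 and -4.62 for PORCN. With the SKOV3 effect turned, it was 4.15, 3.92, -2.40, 4.99 and 4.03 for the former genes and -0.03, 0.63, -1.87, -5.81 and -1.77 for the latter, so the signs for ADD2 and WNT10A and the difference for UNC13D rest on the labels.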

How the results depend on the processing

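The alternatives without the libraries that stood apart, with the turned sign and with identifiers of equal version were chosen after the data were seen, and the others before. The counts of changed genes in each line, of genes that differed between the lines and of genes called in both stayed within 1.5 times under every alternative run, and the log2 fold change of ZIC2 stayed between 1.08 and 1.21 in SKOV3 and between 6.04 and 6.24 in OVCAR3 with each library left out. Leaving out each library in turn gave 6194 to 7119 changed genes in SKOV3 and 11367 to 11917 in OVCAR3, 1821 to 2029 and 2908 to 3005 of at least 2-fold, 9621 to 10238 that differed between the lines and 4222 to 4838 called in both. Without both SKOV3 libraries numbered 3 the SKOV3 counts were 7363 and 1920, and without library 1 of the empty vector and 3 of the ZIC2 vector the OVCAR3 counts were 11838 and 2929. Genes changed at least 2-fold moved to 3039 in SKOV3 and 4391 in OVCAR3 with DESeq2 and its own filtering, and to 3223 and 4870 with no filter on low counts. Both started from 32393 and 34714 genes, against 15102 and 16989, so that with DESeq2 tool and filter changed together and the cause was not tested. The filter's removal adds genes with few counts to those tested. The share of changed genes that were higher in SKOV3 was 49.5%, and it was 58.5% with upper quartile factors, 54.7% with DESeq2 and 47.6% with the replicate number as a block. The share of genes called in both lines with the same sign by label moved from 43.2% to 45.1% with the replicate number as a block, and lay between 40.6% and 45.2% with each library left out; the cause was not tested. The replicate numbers pair the SKOV3 libraries but not the OVCAR3 ones, whose correlations between equal numbers ran from -0.241 to 0.0548 with 0 of 12 libraries closest to their own number. With that block SKOV3 had 8648 changed genes, 1891 of them at least 2-fold, 10468 genes differed between the lines and 5744 were called in both. OVCAR3 had 11244 changed genes, and ZIC4 passed at a log2 of -0.60 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0245) and without library 5 of the empty vector (adjusted p = 0.0389). In SKOV3 the block ended the camera call of the Wnt list (adjusted p = 0.0725) and changed no other call of a named gene or list. Camera with an estimated correlation passed 0 lists in SKOV3 and 0 in OVCAR3, with 2 and 3 at an unadjusted p under 0.05. With the preset correlation 9 and 4 passed. For SKOV3 Hedgehog genes camera's unadjusted p rose from 0.00953 to 0.0203, although their estimated correlation was -0.0126. The size of the correlation was thus not all that changed, and the loss of the calls cannot be put down to it alone. Fry, which tests a list against no change and not against other genes, passed 19 and 28. Over all named genes and alternatives 6313 values stayed on their side of the threshold, 18 lost the call, 2 gained it and none reversed. Most of these genes were named for a large change or a small p in the main fit. Their stability was thus close to fixed in advance and does not measure that of the other calls. Of genes named above, PI3 and S100A8 lost the call with limma-voom. Depth limits genes near 0 counts, whose ratios are bounds or carry wide counting intervals.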

Other observations

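Of the tests in this part, those on splits that part the SKOV3 pairs were chosen only after the results were seen. Single genes named by the rule and not yet described moved with their lists or apart from them. In the SKOV3 libraries labelled knockout, which held more ZIC2 mRNA, PTGS2, which encodes the prostaglandin synthase COX-2, went from 0.262 ± 0.0971 to 8.25 ± 5.20 CPM (SD, n = 6 each), a log2 fold change of 5.03 ± 0.49. The homeobox gene PRRX1 stood at 2.51 ± 0.18, TIMP1, an inhibitor of matrix metalloproteinases, at 1.24 ± 0.10 and the growth factor gene FGF18 at -1.55 ± 0.09. PHGDH and PSAT1, enzymes of serine synthesis, were higher by 0.59 ± 0.09 and 0.31 ± 0.05, and the stress factor gene DDIT3 fell by 0.66 on the log2 scale. In OVCAR3 with the ZIC2 vector, CALB2, the calretinin gene and a mesothelial marker, rose from 0.615 ± 0.144 to 10.8 ± 1.3 CPM, and KDR, a VEGF receptor gene, from 0.592 ± 0.0651 to 6.46 ± 2.65 CPM. CD74, the invariant chain gene of MHC class II, fell from 158 ± 12.1 to 58.4 ± 4.30 CPM. AKR1C3, an aldo-keto reductase gene among the NRF2 targets, stood at 2.41 ± 0.10, GCLC, of glutathione synthesis, at 0.93 ± 0.06 and the amino acid transporter gene SLC7A5 at 0.97 ± 0.07. Each of these genes had an adjusted p of at most 0.000268 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

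Other splits of the 12 libraries of a line into groups of 6 were compared with the real ones, 80 splits in all with the real one. For the number of changed genes, 1 split, the real one, gave as many in SKOV3 (6758, highest other 419) and 1 in OVCAR3 (11677, highest other 0). The real split was also alone for genes changed at least 2-fold in SKOV3 (1 split, 1870, highest other 76) and OVCAR3 (1 split, 2857, highest other 0) and for genes that differed between the lines (1 split, 9808, highest other 2107). Random assignment of these libraries to groups would thus rarely give as many. The other splits mix the real groups, which moves the difference between them into the spread within groups and lowers the counts. Whether the libraries are independent is not known, so chance in the choice of clones or cultures is not excluded. For genes called in both lines (1 split, 4605, highest other 0) the splits decide nothing, since no other split called a gene in OVCAR3. Among the 32 splits that part all 6 SKOV3 pairs of equal number, the real one alone gave 6758 and 1870 genes, and the highest of the others was 0 for both. With these SKOV3 splits, each beside a split of OVCAR3, the real one alone gave 9808 genes that differed between the lines (highest other 1473). Chance could not be excluded for the number of gene lists past camera in SKOV3, where 17 splits gave 9 or more (highest other 14), in OVCAR3, where 61 gave 4 or more (highest other 12), or for the correlation of the effects of the 2 lines across genes, where 50 splits were as far from 0 as -0.06, with SKOV3 as labelled wild type minus labelled knockout (farthest other -0.27). Among the 32 splits that part the SKOV3 pairs, chance could not be excluded for these either, as 5 gave 9 or more lists in SKOV3 (highest other 10) and 12 a correlation as far from 0 (farthest other -0.20). The other splits keep part of the real group difference unless they mix the groups evenly. Their list counts and correlations are thus not a level of chance alone, and the splits cannot decide.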
